A study of Rattus norvegicus with 45 samples.

How the data were processed

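RNA from the livers of adult male Sprague-Dawley rats, 10 weeks old and dosed by gavage, was measured on Affymetrix Rat Genome 230 2.0 arrays, with 1 array per liver and biotin-labelled cRNA as the target, per the labels' protocols. The 45 arrays fall into 9 groups of 5: controls, rats given myclobutanil and rats given triadimefon, each at 6 h, 24 h and 14 days, per the sample titles. The doses, 225 mg/kg/day of myclobutanil and 175 mg/kg/day of triadimefon, are stated for the series and not per sample. The labels conflict on numbers: the series text speaks of 15 livers, the labelling protocol of 3 rats per treatment group, and the titles give 45 arrays with 5 per group. The titles were followed, since the table holds 45 value columns and no pair of them is identical.

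The deposited table holds 1 score per probe set and array, a processed expression value on a log-type scale. Neither the labels nor the file headers state how the authors summarised, background-corrected or normalized these values, or the base of the logarithm. The deposited scores run from -0.98 to 5.69, and the medians of the arrays lie between -0.011 and 0.033, so each array was centred near 0 before deposit. The arrays' 99th percentiles run from 2.69 to 3.52, so their distributions were not made equal. A difference of 1 score unit is 2-fold if the scale is log2 and 2.72-fold if it is the natural logarithm. The design had foreseen log2 or linear values; the values were used as deposited, all differences are given in score units, and no fold is printed for a gene. Arrays have no read depth, and the number of arrays limits the precision. Low-level probe sets sit near the background, and 15290 of those tested had a mean score under 0.

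Probe sets were paired with genes through the annotation deposited for the array. Of the probe sets with 1 gene, 20758 had an identifier found in the RefSeq gene table of the rat assembly GRCr8, which changed 0 symbols and was used for names only. Of 31099 probe sets, 57 Affymetrix control probe sets were left out and 31042 were tested. Among these, 20826 are listed with 1 gene, 436 with several and 9780 with none. A probe set followed from the start is listed with Cyp2b1 and Cyp2b2, so its signal is reported as Cyp2b1 or Cyp2b2. For gene-level statements each of 14217 genes was represented by its probe set of highest mean; 4525 of these genes have more than 1 probe set.

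Differences were tested with limma 3.58.1 in R 4.3.3. The fit had 1 mean per group over all 45 arrays, moderated variances with default settings, and Benjamini-Hochberg adjustment over the probe sets of each comparison. A probe set counted as changed at an adjusted p under 0.05. The comparisons were each compound against the controls of its time, the compounds against each other at each time, the difference of a compound's effect between times, and the controls between times. Errors after the sign ± are the standard errors of that fit, SDs are named as such, and 95% intervals come from the same fit. A total of 30 gene lists for liver functions, stress responses and cell types was fixed with 885 entries, of which 787 were matched. Lists were tested with camera in limma at a preset correlation of 0.01 between genes and adjusted over the lists of a comparison. Beside each call stands the adjusted p with an estimated correlation, which ended 71 of the 72 list calls among the treatment and compound comparisons. A list's direction is relative to all other genes, so it can be called with few or no single members past the threshold.

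Named genes followed a rule. For each treatment comparison they were the 5 highest and 5 lowest differences among changed genes whose 5 treated values all lay on the same side of the control mean, up to 4 changed members of each list described, and a fixed panel of 32 entries. For comparisons between compounds or between times they were the 5 highest, the 5 lowest and the panel. Probe sets with no gene or several genes were passed over. The text names all of the 5 highest and lowest against control at 6 h and only part of the rest. That part was picked after the values were seen, by no fixed rule, and leans to calls that held when any 1 array was left out. The samples, comparisons, lists, rule and most alternatives were chosen before the data were examined. The overlap of the compounds' calls was set against independent lists, against simulated groups that share their controls, and with the controls split between the compounds.

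Alternatives changed 1 choice at a time. They were quantile normalization, a shift of every array to the same median, only probe sets above the median level, only the groups compared in the fit, a variance trend with robust moderation, array weights, a block for the replicate numbers, the ending of the array file name, a difference of at least 1.5-fold if the scale is log2, an adjusted p under 0.01, and each array left out in turn. The file-name ending is 11 on 36 arrays, 12 on 7, 21 on 1 and 31 on 1; the labels do not say what it stands for. Ending 12 is on myclobutanil arrays 3, 4 and 5 and triadimefon arrays 1, 2 and 3 at 6 h and on myclobutanil array 3 at 14 days, and no control array has it. It was used as a covariate and by repeating comparisons within arrays of 1 ending. Replicate numbers did not pair arrays: mean correlations of the arrays with the same number, after group means were taken off, were -0.07 to 0.25. Chosen after seeing the data were the fit without the 4 arrays of 99th percentile above 3.2 (control 2 at 6 h, control 2 at 24 h, and myclobutanil 2 and 4 at 14 days), quantile normalization together with an estimated correlation, and the file-name ending for lists and named genes at 6 h. Pseudocounts were planned for linear values only and were not needed.

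The steps were tested in 10 simulations of independent probe sets, 200 of 31042 changed. For myclobutanil against control at 24 h, 92.4% of changes of 0.25 units, 98.5% of 0.5 units and 99.7% of 1 unit were recovered, and 5.51% of calls were false. For triadimefon against myclobutanil at 24 h they were 90.7%, 97.8% and 99.7%, with 4.29% false. For the myclobutanil effect at 24 h against 6 h they were 82.2%, 95.4% and 99.5%, with 4.89% false. A cell cycle list shifted by 0.2 units in the first of these was called in 10 of 10. Other lists gave 0 calls in 290 tests, which leaves correlated genes untested. Figures were drawn with matplotlib 3.10.9.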

Results

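Liver RNA of adult male rats was measured on 45 arrays, by the sample titles 9 groups of 5 rats. Other labels conflict (15 livers in the series text, 3 rats per group in the protocol), so a rat below is an array so titled, and arrays from shared animals would not be independent. The rats had received myclobutanil at 225 mg/kg/day or triadimefon at 175 mg/kg/day, or served as controls, and livers were taken at 6 h, 24 h or 14 days. Both compounds are triazole fungicides, a class made to block the fungal enzyme that removes a methyl group from sterol precursors. The doses differ, so a difference between the compounds is a difference between these treatments and not between equal doses. Values are deposited scores on a log-type scale of unstated base, and differences below are in score units, in which 1 unit is 2-fold if the base is 2. The bright end of the scale varied between arrays: among probe sets of mean score above 3, the SD within groups was 0.218 as deposited and 0.0581 after quantile normalization, against 0.0399 and 0.0363 among those under 0. Counts are therefore given as deposited and after quantile normalization.

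Each compound was compared with the controls of its time, to ask which liver genes respond and when. Of 31042 probe sets, myclobutanil raised 84 and lowered 34 at 6 h, raised 946 and lowered 1682 at 24 h, and raised 228 and lowered 18 at 14 days. Triadimefon raised 229 and lowered 55 at 6 h, raised 694 and lowered 1784 at 24 h, and raised 1207 and lowered 869 at 14 days. After quantile normalization the counts higher and lower were 266 and 175, 1878 and 1483, and 222 and 124 for myclobutanil, and 530 and 298, 1381 and 1421, and 1446 and 1393 for triadimefon. The excess of lowered probe sets with myclobutanil at 24 h therefore turned into an excess of raised ones, and no majority direction is stated for that comparison. Most changes were small: the median size of the called differences ran from 0.12 to 0.28 units, and between 2 and 18 probe sets per comparison passed 1 unit. Of 30 gene lists tested in these comparisons and between the compounds, 72 list calls passed, of which 42 held in every repeat with 1 array left out and 30 did not; not every call is described below.

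**Figure D1:**
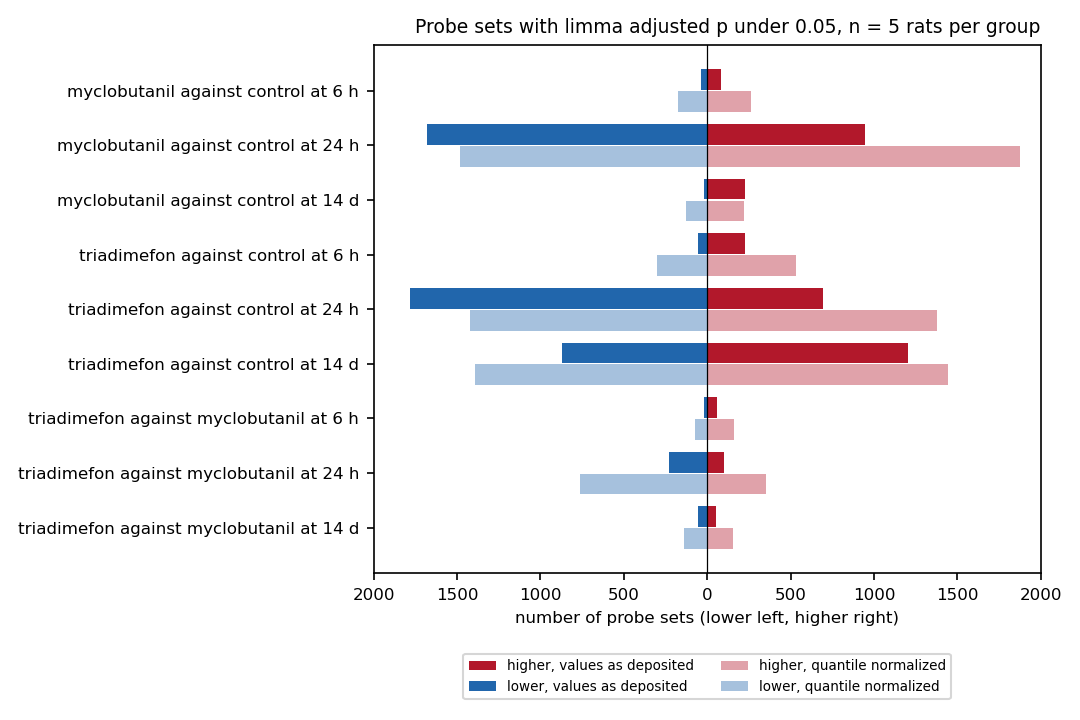
Number of probe sets higher (right) and lower (left) in each of the treatment comparisons and the comparisons of the compounds, as deposited and after quantile normalization. With myclobutanil at 24 h the deposited values give 946 higher and 1682 lower, and quantile normalization gives 1878 and 1483.

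With myclobutanil at 6 h few genes of drug handling passed. The probe set of Cyp2b1 or Cyp2b2, drug-metabolising cytochromes that the constitutive androstane receptor (CAR) switches on, rose most, and Abcb1a, which pumps drugs out of cells, rose with it. Insig2, which restrains sterol synthesis, and Cyp26b1, which breaks down retinoic acid, also rose. Gadd45b, a stress-induced growth regulator, and Hmox1, which breaks down haem, were higher as well. Gclm, a subunit of the enzyme that limits glutathione synthesis, fell, as did Osbpl11, a lipid-binding protein.

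In numbers, Cyp2b1 or Cyp2b2 rose by 2.44 ± 0.21 (adjusted p = 8.2e-10), Insig2 by 0.91 ± 0.13 (4.9e-05), Gadd45b by 0.88 ± 0.11 (2.7e-06), Abcb1a by 0.73 ± 0.09 (4.4e-06), Cyp26b1 by 0.69 ± 0.12 (0.002) and Hmox1 by 0.45 ± 0.07 (9.8e-05). Gclm fell by 0.63 ± 0.07 (adjusted p = 2.1e-07) and Osbpl11 fell by 0.48 ± 0.09 (0.0051). For each of these genes 5 of 5 treated rats lay on that side of the control mean. Arrays 3, 4 and 5 of this group carry a file-name ending, 12, that no control array has. Among arrays of ending 11 alone, with 3 control and 2 treated arrays, the differences were 2.03 for Cyp2b1 or Cyp2b2 (adjusted p = 0.0027), 1.06 for Insig2 (0.027), 0.82 for Gadd45b (0.027), 0.69 for Hmox1 (2.3e-05) and -0.54 for Gclm (0.014). Abcb1a (0.56, 0.18), Cyp26b1 (0.80, 0.079) and Osbpl11 (-0.44, 0.41) kept their direction there and did not pass. With the ending as a covariate the count of changed probe sets was 50 in place of 118, and among arrays of ending 11 it was 20. The P450 list as a whole did not pass at 6 h: 2 of 39 rose and 0 fell, or 3 and 0 adjusted over the list alone, with a mean of 0.05, a median of -0.004 and a camera adjusted p of 0.21. After quantile normalization 6 rose and 0 fell, with a mean of 0.107 (adjusted p = 0.00014).

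Lists of lipid genes passed with myclobutanil at 6 h on small mean shifts, with almost no single member past the threshold, and none passed with an estimated correlation. Of 22 measured genes of sterol synthesis and uptake 1 rose, Insig2, and 0 fell, or 1 and 5 adjusted over the list alone, and the mean difference was -0.113 (camera adjusted p = 0.0005, adjusted p = 0.96 with an estimated correlation). Fatty acid synthesis had 0 of 25 changed, or 0 higher and 1 lower adjusted over the list alone, with a mean of -0.17 (0.00025, and 0.96 with an estimated correlation). Fatty acid oxidation had 0 of 46 changed, or 0 higher and 6 lower adjusted over the list alone, with a mean of -0.113 (7.5e-05, and 0.96 with an estimated correlation). Counts of 0 here come from limma, which gave 2624 probe sets at an unadjusted p under 0.05 in the whole comparison. Among arrays of ending 11 the means were -0.088 for the sterol list (0.0012), -0.032 for fatty acid synthesis (0.092) and -0.023 for fatty acid oxidation (0.042), and with the ending as a covariate they were -0.119 (0.0013), -0.159 (0.0015) and -0.098 (0.0013). Hepatocyte secretory and identity genes had a mean of -0.135 with 0 of 29 changed, by limma and also adjusted over the list alone (0.024, and 0.96 with an estimated correlation). This call did not hold after quantile normalization (-0.007, adjusted p = 0.9), its mean was 0.115 among arrays of ending 11 and -0.151 with the ending as a covariate (0.01), and it was lost without control 2 (-0.056), control 3 (-0.016), myclobutanil 1 (-0.093) or myclobutanil 3, with adjusted p up to 0.9.

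Triadimefon at 6 h also raised the Cyp2b1 or Cyp2b2 signal, and it raised several chaperone genes. Cyp2b1 or Cyp2b2 rose with Cyp26a1 and Cyp26b1, which clear retinoic acid. Creld2, Hyou1 and Manf, which serve protein folding in the endoplasmic reticulum, rose, as did Hsph1, Stip1 and Ahsa1, partners of the cytosolic heat shock proteins. Gclm fell here too, with Slc13a4, a sulfate transporter.

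The rise was 2.38 ± 0.21 for Cyp2b1 or Cyp2b2 (adjusted p = 1.8e-09), 0.75 ± 0.10 for Creld2 (adjusted p = 7.9e-06), 0.62 ± 0.10 for Hsph1 (adjusted p = 0.00047), 0.55 ± 0.08 for Hyou1 (adjusted p = 3.7e-05) and 0.45 ± 0.07 for Cyp26a1 (adjusted p = 0.00037), each in 5 of 5 treated rats. Gclm fell by 0.48 ± 0.07 (adjusted p = 3e-05), also in 5 of 5. Among heat shock genes 5 of 17 rose and 0 fell, or 10 and 0 adjusted over the list alone, with a mean of 0.212 (camera adjusted p = 2.5e-11, adjusted p = 0.17 with an estimated correlation). In the list of endoplasmic reticulum stress and amino acid response 5 of 34 rose and 0 fell, or 8 and 1 adjusted over the list alone, with a mean of 0.145 (3.4e-05, and 0.96 with an estimated correlation). The sterol list had 1 of 22 higher and 0 lower, Insig2, with the same counts adjusted over the list alone and a mean of 0.155 (0.00017, and 0.96 with an estimated correlation). Fatty acid oxidation had 0 of 46 higher and 2 lower, or 1 and 8 adjusted over the list alone, with a mean of -0.097 (0.00019, and 0.96 with an estimated correlation). Insig2 itself (0.56, adjusted p = 0.022) lost its call without any of 7 arrays, control 1, 3 or 4 and triadimefon 1, 2, 3 or 5, with differences down to 0.52 and adjusted p up to 0.074. Hspa1a, an inducible heat shock protein, was called at 6 h with myclobutanil (0.43, adjusted p = 0.039) and with triadimefon (0.40, adjusted p = 0.042), in 5 of 5 rats each. Among arrays of ending 11 it was 0.53 (0.00034) and 0.15 (0.89), and with the ending as a covariate 0.37 (0.24) and 0.34 (0.22). Its myclobutanil call was lost without any control or myclobutanil 1, 2 or 4 (down to 0.39, adjusted p up to 0.11), and its triadimefon call without any control or triadimefon 1 or 3 (down to 0.20, adjusted p up to 0.1). The heat shock list with myclobutanil had 1 of 17 higher and 0 lower, also adjusted over the list alone, with a mean of 0, a median of -0.031 and a camera adjusted p of 0.88.

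Arrays 1, 2 and 3 of the triadimefon group at 6 h carry the ending 12. Among arrays of ending 11, with 3 control and 2 treated arrays, Cyp2b1 or Cyp2b2 (2.02, adjusted p = 0.0048) and Cyp26a1 (0.44, 0.014) passed, and Creld2 (0.59, 0.12), Hyou1 (0.51, 0.069), Hsph1 (0.43, 0.76) and Gclm (-0.39, 0.26) kept their direction without passing. So did Cyp26b1 (0.70, 0.23), Manf (0.52, 0.46), Stip1 (0.25, 0.84), Ahsa1 (0.25, 0.76) and Slc13a4 (-0.43, 0.72). The list means there were 0.177 for heat shock (1.1e-06), 0.159 for endoplasmic reticulum stress (0.00067), 0.256 for the sterol list (1.4e-08) and -0.033 for fatty acid oxidation (0.48). With the ending as a covariate they were 0.192 (6.5e-08), 0.141 (0.00052), 0.149 (0.0019) and -0.083 (0.0029), Insig2 was 0.58 (0.085), and the count of probe sets was 110 in place of 284. Within ending 11 the count was 9. The count also moved without control 1 (173), control 3 (174), triadimefon 1 (130) or triadimefon 2 (136). Erythroid markers, 0 of 11 changed by limma, which gave 3534 probe sets at an unadjusted p under 0.05, and 0 adjusted over the list alone, had a mean of -0.044 (0.036, and 0.96 with an estimated correlation). That call was lost after quantile normalization (-0.042, adjusted p = 0.11), and without control 3 (-0.017, adjusted p = 0.23) or triadimefon 2, 3 or 5.

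Hamp, the iron hormone hepcidin, fell most with both compounds at 6 h, and Alas1, which starts haem synthesis, was among the highest. With myclobutanil Hamp fell by 1.95 ± 0.38 (adjusted p = 0.0057), Tsc22d1, a transcription regulator, fell by 0.75 (0.011), Ptger3, a prostaglandin receptor, fell by 0.43 (0.0083), Alas1 rose by 0.94 ± 0.17 (0.0021) and Por, which feeds electrons to P450s, by 0.70 (0.048), each in 5 of 5 rats. None passed with the ending as a covariate (-1.78, 0.093; -0.65, 0.16; -0.41, 0.097; 0.82, 0.065; 0.67, 0.2), or within ending 11 (-1.78, 0.33; -0.50, 0.68; -0.43, 0.39; 0.86, 0.31; 0.67, 0.57). Por kept the call only without control 3 or myclobutanil 3 (else up to 0.18). Tsc22d1 lost it without control 2 or myclobutanil 3 (up to 0.07). No other probe set of Tsc22d1, Ptger3 or Por passed. With triadimefon Hamp fell by 1.51 ± 0.38 (0.041), Cyp8b1 fell by 0.70 (0.01), Cyp4a3, which oxidises fatty acids, fell by 0.63 (0.022), Alas1 rose by 0.81 ± 0.17 (0.0086), Por by 0.66 (0.042) and Tsku, a secreted protein, by 0.63 (0.025), each in 5 of 5 rats. None passed with the covariate (-1.34, 0.21; -0.59, 0.13; -0.61, 0.12; 0.69, 0.11; 0.63, 0.17; 0.53, 0.21), and within ending 11 the signs held without passing (-0.82, -0.36, -0.60, 0.89, 0.77 and 0.83). Calls were lost without any control or triadimefon 1 or 2 for Hamp (up to 0.18), triadimefon 2 for Cyp8b1 (0.063), control 2 or 3 or triadimefon 1 or 5 for Cyp4a3 (up to 0.085), control 1 for Alas1 (0.051), any array but control 3 for Por (up to 0.16), and control 1 or 5 or triadimefon 1, 2 or 5 for Tsku (up to 0.13).

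The compounds were set against each other at 6 h. Hsph1 and Creld2, which serve protein folding, were higher with triadimefon. Hmox1 was lower with triadimefon, as were Cirbp and Rbm3, RNA-binding proteins that respond to cold. For Cyp2b1 or Cyp2b2 no difference was detected.

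Of 31042 probe sets 62 were higher and 16 lower with triadimefon, and 159 and 75 after quantile normalization. The count of 78 fell without myclobutanil 1 (46), 2 (50) or 3 (45) or triadimefon 1 (24) or 2 (35). Creld2 differed by 0.69 ± 0.10 (adjusted p = 0.0002), Hsph1 by 0.66 ± 0.10 (0.00053), Hmox1 by -0.46 ± 0.07 (0.0002), Rbm3 by -0.37 ± 0.05 (0.0002) and Cirbp by -0.22 ± 0.03 (0.0002), each in 5 of 5 triadimefon rats. Among arrays of ending 11 these were 0.56 (0.25), 0.50 (0.52), -0.75 (3e-05), -0.50 (0.0017) and -0.25 (0.047), and among arrays of ending 12 they were 0.77 (0.082), 0.77 (0.00075), -0.28 (0.15), -0.29 (0.11) and -0.20 (0.082). The counts were 1 higher and 7 lower within ending 11, so the majority turned, and 25 higher and 1 lower within ending 12. Of sterol genes 4 of 22 were higher and 0 lower, or 14 and 1 adjusted over the list alone, with a mean of 0.268 (camera adjusted p = 4e-16, adjusted p = 0.1 with an estimated correlation). Its mean was 0.344 within ending 11 (2.7e-16) and 0.218 within ending 12 (3.5e-07). Of heat shock genes 6 of 17 were higher and 0 lower, or 7 and 0 adjusted over the list alone, with a mean of 0.212 (5.2e-13, and 0.1 with an estimated correlation), and 0.127 (0.0019) and 0.269 (3.9e-09) within the endings. Cyp2b1 or Cyp2b2 differed by -0.06 with a 95% interval of -0.49 to 0.36 (adjusted p = 0.99).

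Other lists passed between the compounds at 6 h on few or no members. Endoplasmic reticulum stress genes had 3 of 34 higher and 0 lower, or 7 and 1 adjusted over the list alone, with a mean of 0.105 (camera adjusted p = 0.022, adjusted p = 0.99 with an estimated correlation). This call was lost without myclobutanil 1 (0.085, adjusted p = 0.12) or triadimefon 1 (0.077, 0.079), and the means within endings were 0.067 (0.11) and 0.131 (0.15). The list of thyroid hormone metabolism had 0 of 17 changed, by limma with 2307 probe sets at an unadjusted p under 0.05, 0 adjusted over the list alone, and a mean of -0.038 (0.044, and 0.99 with an estimated correlation). It was lost in 9 of the 10 repeats with an array left out, all but that without myclobutanil 3, with means from -0.052 to -0.018 and adjusted p up to 0.13.

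At 24 h, myclobutanil raised genes of cell division. Cdk1, Mki67, Mcm6, Pcna and Stmn1, which drive or mark DNA replication and mitosis, all rose. Of 18 markers of Kupffer cells, the macrophages of the liver, and other macrophages 13 fell, among them Clec4f, a receptor of these cells, Cd5l, and the complement genes C1qa and C1qc. That list call did not pass with an estimated correlation (adjusted p = 0.29), and the endothelial and stellate lists passed downward too. Cyp7a1 and Cyp8b1, which make bile acids, fell, while Aldh1a1, Ces2c, Ugt2b1 and Slco1a4 rose, from drug-handling lists whose members went both ways. Glul, which makes glutamine around the central vein, and Pklr and Pc, enzymes of glucose handling, fell.

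Of the cell cycle list 37 of 43 genes rose and 0 fell, or 38 and 1 adjusted over the list alone, with a mean difference of 0.346 (camera adjusted p = 8.1e-50, adjusted p = 0.012 with an estimated correlation). It was the only call among 72 in the treatment and compound comparisons that passed with an estimated correlation. Mcm6 rose by 0.74 ± 0.08 (adjusted p = 3.6e-08), Cdk1 by 0.68 ± 0.11 (6.2e-05), Pcna by 0.63 ± 0.07 (6.1e-08) and Mki67 by 0.51 ± 0.10 (0.0005), each in 5 of 5 treated rats. Among Kupffer and other macrophage markers 0 of 18 rose and 13 fell, or 0 and 15 adjusted over the list alone, with a mean of -0.307 (4.2e-11, and 0.29 with an estimated correlation). Clec4f fell by 0.79 ± 0.12 (adjusted p = 2.9e-05), C1qa fell by 0.51 ± 0.08 (4.5e-05) and C1qc fell by 0.47 ± 0.09 (0.00057), each in 5 of 5 rats. Sinusoidal endothelial markers had 0 of 16 higher and 4 lower, or 0 and 7 adjusted over the list alone, with a mean of -0.095 (0.0051, and 0.7 with an estimated correlation). Stellate cell markers had 0 of 22 higher and 2 lower, also adjusted over the list alone, with a mean of -0.108 (0.04995, and 0.7 with an estimated correlation), and lost the call without control 2, 3 or 5 or myclobutanil 1, 2 or 3, with means from -0.114 to -0.081 and adjusted p up to 0.13.

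Several lists of metabolism and stress also passed with myclobutanil at 24 h. Bile acid genes had 0 of 23 higher and 3 lower, or 0 and 6 adjusted over the list alone, with a mean of -0.271 (camera adjusted p = 0.0046, adjusted p = 0.7 with an estimated correlation). Glucose metabolism had 0 of 31 higher and 5 lower, or 1 and 12 adjusted over the list alone, with a mean of -0.236 (0.001, and 0.7 with an estimated correlation). Periportal hepatocyte genes had 1 of 19 higher and 5 lower, or 1 and 12 adjusted over the list alone, with a mean of -0.3 (0.001, and 0.7 with an estimated correlation). Fatty acid synthesis had 0 of 25 higher and 4 lower, or 1 and 8 adjusted over the list alone, with a mean of -0.224 (0.024, and 0.74 with an estimated correlation). That call was lost after quantile normalization (-0.137, adjusted p = 0.056) and without control 2 (-0.145, 0.094) or myclobutanil 1 (-0.218, 0.051). NRF2 and oxidative stress genes had 8 of 37 higher and 1 lower, or 9 and 2 adjusted over the list alone, with a mean of 0.102 (0.001, and 0.7 with an estimated correlation). Heat shock genes had 6 of 17 higher and 0 lower, or 7 and 0 adjusted over the list alone, with a mean of 0.177 (2.6e-07, and 0.29 with an estimated correlation). The sterol list had 2 of 22 higher and 0 lower, also adjusted over the list alone, with a mean of 0.099 (0.0033, and 0.7 with an estimated correlation). Hepatocyte secretory genes had 0 of 29 higher and 1 lower, and 0 adjusted over the list alone, with a mean of -0.226 (0.015, and 0.78 with an estimated correlation), and lost the call without control 2 (-0.093, 0.19) or myclobutanil 5 (-0.172, 0.067).

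Cyp2b1 or Cyp2b2 rose by 2.59 ± 0.21 (adjusted p = 6.7e-11), Aldh1a1 by 1.41 ± 0.20 (6.3e-06), Ces2c by 1.27 ± 0.10 (1.1e-11) and Slco1a4 by 0.88 ± 0.09 (3.6e-08). Cyp8b1 fell by 1.60 ± 0.15 (adjusted p = 2.5e-09), Cyp7a1 fell by 1.60 ± 0.27 (9.3e-05), Fmo1, a flavin monooxygenase, fell by 1.0 ± 0.11 (9.4e-08) and Glul fell by 0.66 ± 0.12 (0.0002), each in 5 of 5 treated rats. Without myclobutanil 2 the count of changed probe sets was 1717 in place of 2628. The drug-metabolising P450 list went both ways, 7 of 39 higher and 5 lower, or 8 and 6 adjusted over the list alone, with a mean of 0.072, a median of -0.066 and a camera adjusted p of 0.2. After quantile normalization it was 15 higher and 3 lower with a mean of 0.196 (0.00027). Conjugating enzymes had 5 of 38 higher and 8 lower, or 5 and 9 adjusted over the list alone, with a mean of -0.003, a median of 0.003 and an adjusted p of 0.46, and 13 higher and 7 lower after quantile normalization.

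**Figure D2:**
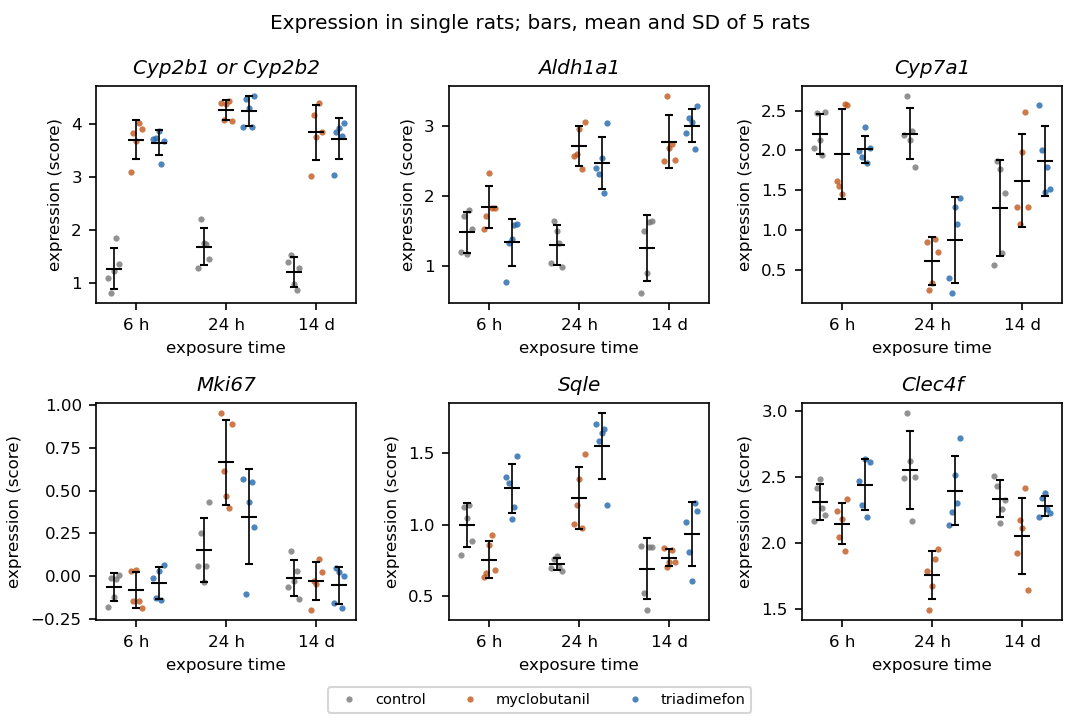
Scores of single rats, with the mean and SD of the 5 rats of each group, for Cyp2b1 or Cyp2b2, Aldh1a1, Cyp7a1, Mki67, Sqle and Clec4f in controls and both treatments at 6 h, 24 h and 14 days. The Cyp2b1 or Cyp2b2 signal was higher by 2.38 to 2.63 units in every treated group, and Mki67 rose by 0.51 with myclobutanil at 24 h.

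At 24 h, triadimefon raised 14 of 22 sterol genes, a list call that did not pass with an estimated correlation (adjusted p = 0.27). Sqle, Idi1, Msmo1, Lss and Cyp51, enzymes along that pathway, rose, Cyp51 being the mammalian counterpart of the fungal target. Srebf1, a regulator of fatty acid synthesis, and Thrsp, which promotes it, fell. Ccnd1, which moves cells toward DNA replication, and Mcm4 rose. Cyp7a1, Cyp8b1 and Glul fell, as they did with myclobutanil.

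Of the sterol list 14 of 22 genes rose and 0 fell, or 16 and 0 adjusted over the list alone, with a mean of 0.33 (camera adjusted p = 2.3e-15, adjusted p = 0.27 with an estimated correlation). Idi1 rose by 0.89 ± 0.14 (adjusted p = 8.7e-05), Sqle by 0.82 ± 0.11 (2.5e-06), Msmo1 by 0.80 ± 0.11 (1.6e-05) and Cyp51 by 0.47 ± 0.10 (0.0027), each in 5 of 5 treated rats. Of the fatty acid synthesis list 2 of 25 rose and 8 fell, or 2 and 10 adjusted over the list alone, with a mean of -0.32 (0.0029, and 0.92 with an estimated correlation). Thrsp fell by 1.20 ± 0.23 (adjusted p = 0.00089) and Srebf1 fell by 0.85 ± 0.14 (0.00011), each in 5 of 5. Of the cell cycle list 15 of 43 rose and 0 fell, or 24 and 0 adjusted over the list alone, with a mean of 0.158 (1.1e-15, and 0.54 with an estimated correlation). Heat shock genes had 4 of 17 higher and 0 lower, or 5 and 1 adjusted over the list alone, with a mean of 0.082 (0.0077, and 0.92 with an estimated correlation). Transporters had 6 of 24 higher and 3 lower, or 7 and 4 adjusted over the list alone, with a mean of 0.09 (0.0077, and 0.92 with an estimated correlation). Cyp2b1 or Cyp2b2 rose by 2.56 ± 0.21 (adjusted p = 2e-10) and Cyp7a1 fell by 1.34 ± 0.27 (0.0014), each in 5 of 5.

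Several calls with triadimefon at 24 h leaned on single rats. Fatty acid oxidation genes had 8 of 46 higher and 0 lower, or 9 and 1 adjusted over the list alone, with a mean of 0.078 (camera adjusted p = 0.0029, adjusted p = 0.92 with an estimated correlation), and a mean of -0.011 (0.22) without triadimefon 5. Of its members Eci1, an enoyl-CoA isomerase, rose by 0.57 ± 0.13 (adjusted p = 0.0045). The list of pancreas, fat, gut and muscle contamination markers had 0 of 24 higher and 1 lower, also adjusted over the list alone, with a mean of 0.094 (0.0077, and 0.92 with an estimated correlation), -0.02 (0.21) without triadimefon 2, and an adjusted p of 0.11 after quantile normalization. Periportal hepatocyte genes had 1 of 19 higher and 3 lower, or 1 and 8 adjusted over the list alone, with a mean of -0.22 (0.01, and 0.92 with an estimated correlation). Glucose metabolism had 1 of 31 higher and 8 lower, or 1 and 11 adjusted over the list alone, with a mean of -0.187 (0.039, and 0.92 with an estimated correlation), and was lost without control 4 or 5 or triadimefon 1 or 3, with means from -0.198 to -0.153 and adjusted p up to 0.08. The count of 2478 changed probe sets was 1159 without control 2 and 1484 without triadimefon 1. Male-predominant liver genes had 0 of 19 higher and 4 lower, also adjusted over the list alone, with a mean of -0.188 and an adjusted p of 0.063. The P450 list had 7 of 39 higher and 4 lower, or 8 and 5 adjusted over the list alone, with a mean of 0.099 and a median of -0.007 (0.073), and 14 higher and 4 lower after quantile normalization (0.211, 7.6e-05).

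Set against each other at 24 h, the compounds parted in some genes of cell division, macrophages and sterol synthesis. Of the cell cycle genes 12 of 43 were lower with triadimefon than with myclobutanil, and 5 of 18 Kupffer markers, among them Clec4f, and 4 of 22 sterol genes were higher. As lists all 3 passed at the preset correlation and not with an estimated correlation (adjusted p = 0.24, 0.25 and 0.25). Gclc, which makes the glutathione precursor, and the tubulin Tubb5 were lower with triadimefon, and Acss2, which makes acetyl-CoA, and Gadd45b were higher.

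Of 31042 probe sets 100 were higher and 228 lower with triadimefon, and 352 and 765 after quantile normalization. The count of 328 changed without myclobutanil 1 (160), 2 (159) or 5 (201) or triadimefon 2 (178) or 5 (199). Of the cell cycle list 0 of 43 were higher and 12 lower, or 1 and 33 adjusted over the list alone, with a mean of -0.188 (camera adjusted p = 6.2e-26, adjusted p = 0.24 with an estimated correlation). Of Kupffer markers 5 of 18 were higher and 0 lower, or 13 and 1 adjusted over the list alone, with a mean of 0.191 (4.9e-11, and 0.25 with an estimated correlation). The sterol list had 4 of 22 higher and 0 lower, or 13 and 0 adjusted over the list alone, with a mean of 0.232 (4.8e-11, and 0.25 with an estimated correlation). Fatty acid oxidation had 3 of 46 higher and 0 lower, or 9 and 0 adjusted over the list alone, with a mean of 0.15 (1.9e-08, and 0.7 with an estimated correlation). Clec4f differed by 0.64 ± 0.12 (adjusted p = 0.0049), Acss2 by 0.59 ± 0.09 (0.0013), Gadd45b by 0.57 ± 0.11 (0.0032), Tubb5 by -0.45 (adjusted p = 0.0051) and Gclc by -0.45 ± 0.08 (0.0027), each in 5 of 5 triadimefon rats. Cyp2b1 or Cyp2b2 differed by -0.03 with a 95% interval of -0.46 to 0.39 (adjusted p = 0.98), and Cyp3a23-3a1 by 0.04 with an interval of -0.26 to 0.34.

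After 14 days, both compounds raised some genes of drug metabolism, conjugation and antioxidant defence. Gsta3 and Gstm3, glutathione transferases, Ugt2b1, which attaches glucuronic acid, Akr7a3 and Ephx1, which disarm reactive products, and Abcc3, an exporter of conjugates, all rose. Epcam, a marker of bile duct and progenitor cells, also rose with both. With triadimefon Mt2A, a metal-binding protein, and the sterol exporters Abcg5 and Abcg8 rose, while Apoa4, an apolipoprotein, Plin2, which coats fat droplets, and Angptl4, a lipase inhibitor, fell. Cd36, which takes up fatty acids, rose.

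For myclobutanil at 14 days the P450 list had 7 of 39 higher and 0 lower, or 8 and 0 adjusted over the list alone, with a mean of 0.312 (camera adjusted p = 9.9e-07, adjusted p = 0.93 with an estimated correlation). Conjugating enzymes had 5 of 38 higher and 0 lower, or 10 and 0 adjusted over the list alone, with a mean of 0.217 (7.1e-05, and 0.93 with an estimated correlation). NRF2 and oxidative stress genes had 7 of 37 higher and 0 lower, or 16 and 0 adjusted over the list alone, with a mean of 0.225 (3.9e-08, and 0.93 with an estimated correlation). The cell cycle list, by contrast with 24 h, had 0 of 43 changed by limma, with 4070 probe sets at an unadjusted p under 0.05, 0 adjusted over the list alone, and a mean of -0.036 (0.00081, and 0.93 with an estimated correlation). Cyp2b1 or Cyp2b2 rose by 2.63 ± 0.21 (adjusted p = 7.6e-11), Ugt2b1 by 1.66 ± 0.19 (3.8e-07), Gsta3 by 1.35 ± 0.16 (8.9e-07), Abcc3 by 0.81 ± 0.10 (1.1e-06) and Epcam by 0.44 ± 0.06 (2e-05), each in 5 of 5 treated rats. The count of 246 changed without control 4 (108), control 5 (145) or myclobutanil 2 (128), 4 (73) or 5 (408).

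With myclobutanil at 14 days fatty acid synthesis had 1 of 25 higher and 0 lower, or 6 and 0 adjusted over the list alone, with a mean of 0.208 (camera adjusted p = 0.0087, adjusted p = 0.93 with an estimated correlation), 0.178 (0.085) without control 1, 0.141 (0.11) without control 4 and an adjusted p of 0.065 after quantile normalization. Lymphocyte and granulocyte markers had 0 of 19 changed by limma, 0 adjusted over the list alone, and a mean of -0.006 (0.034, and 0.93 with an estimated correlation), lost after quantile normalization (0.34) and without control 1 or 4 or myclobutanil 5, with means from -0.006 to 0.002 and adjusted p up to 0.13. Cholangiocyte markers had 3 of 15 higher and 0 lower, also adjusted over the list alone, with a mean of 0.074 and an adjusted p of 0.55.

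For triadimefon at 14 days the P450 list had 6 of 39 higher and 0 lower, or 9 and 1 adjusted over the list alone, with a mean of 0.254 (camera adjusted p = 0.0014, adjusted p = 0.95 with an estimated correlation). Conjugating enzymes had 8 of 38 higher and 0 lower, also adjusted over the list alone, with a mean of 0.199 (0.0014, and 0.95 with an estimated correlation). NRF2 genes had 11 of 37 higher and 0 lower, or 13 and 0 adjusted over the list alone, with a mean of 0.227 (5.8e-06, and 0.95 with an estimated correlation). Cyp2b1 or Cyp2b2 rose by 2.52 ± 0.21 (adjusted p = 7.9e-11), Aldh1a1 by 1.75 ± 0.20 (2.6e-07), Mt2A by 1.65 ± 0.30 (0.00067), Gsta3 by 1.55 ± 0.16 (1.2e-08), Abcc3 by 1.13 ± 0.10 (1.1e-10) and Abcg5 by 0.86 ± 0.16 (0.00078), each in 5 of 5 treated rats. Apoa4 fell by 0.94 ± 0.19 (adjusted p = 0.002), Angptl4 fell by 0.73 ± 0.16 (0.005), Plin2 fell by 0.65 ± 0.15 (0.0076) and Cd36 rose by 0.50 ± 0.11 (0.0046), each in 5 of 5. Fatty acid synthesis had 3 of 25 higher and 3 lower, or 4 and 3 adjusted over the list alone, with a mean of -0.056 and a camera adjusted p of 0.46. Fatty acid oxidation had 1 of 46 higher and 4 lower, or 1 and 5 adjusted over the list alone, with a mean of -0.032 and an adjusted p of 0.38. The count of 2076 changed without control 2 (1014) or triadimefon 1 (1337), 4 (1164) or 5 (1370).

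With triadimefon at 14 days Nr1d1 and Nr1d2, repressors in the daily clock, rose, and Cry1, another part of it, fell. Nr1d2 rose by 0.94 ± 0.10 (adjusted p = 9.3e-08), Nr1d1 rose by 0.56 ± 0.09 (5.8e-05) and Cry1 fell by 0.53 ± 0.08 (2.1e-05), each in 5 of 5 treated rats. Of the circadian list 3 of 22 rose and 2 fell, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.8). The lists of thyroid hormone metabolism (3 of 17 higher, 0 lower, also adjusted over the list alone, mean 0.121, 0.27), steroid hormone metabolism (3 of 32 higher, 2 lower, or 4 and 5 adjusted over the list alone, mean 0.063, median -0.029, 0.45), retinoid metabolism (2 of 33 higher, 1 lower, also adjusted over the list alone, mean 0.059, median -0.001, 0.85), nuclear receptors (2 of 32 higher, 2 lower, or 3 and 2 adjusted over the list alone, mean 0.016, 0.75) and acute phase genes (4 of 40 higher, 0 lower, or 4 and 1 adjusted over the list alone, mean 0.054, median -0.014, 0.45) did not pass. For nuclear receptors camera's direction was down while the mean was above 0. Sinusoidal endothelial markers had 2 of 16 higher and 0 lower, or 4 and 0 adjusted over the list alone, with a mean of 0.064 (0.038, and 0.95 with an estimated correlation). That call was lost after quantile normalization (0.033, adjusted p = 0.08) and without control 2 or 4 or triadimefon 4, with means from 0.055 to 0.06 and adjusted p up to 0.078.

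Other genes were among the highest and lowest later. At 24 h, Inmt, a methyltransferase (1.31 with myclobutanil, 1.02 with triadimefon), Alas1 (0.94 and 1.11) and, with triadimefon, Cyp3a9, a P450 (1.19), rose, and Stac3, a muscle gene (-1.07 and -1.55), and Tsc22d1 (-1.05 and -1.13) fell, each in 5 of 5 treated rats, though another probe set of Tsc22d1 was called the other way with myclobutanil. Scd, which desaturates fatty acids, fell with triadimefon (-1.09, adjusted p = 0.027), not without control 2 or triadimefon 1, 3 or 5 (up to 0.12). At 14 days Spin2b fell with both (-0.69 and -0.69), and Slc6a6, the taurine transporter, with triadimefon (-0.78).

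Between the compounds at 14 days, Nr1d1, Nr1d2, Abcg5 and Abcg8 were higher with triadimefon and Cry1 was lower. Of 31042 probe sets 51 were higher and 52 lower, and 154 and 138 after quantile normalization, so neither direction prevailed. The count of 103 changed without myclobutanil 2 (54), 3 (64) or 4 (40) or triadimefon 2 (64), 4 (23) or 5 (63). Abcg5 differed by 1.0 ± 0.16 (adjusted p = 0.00082), Nr1d2 by 0.83 ± 0.10 (7.1e-06), Abcg8 by 0.82 ± 0.14 (0.0019), Nr1d1 by 0.52 ± 0.09 (0.0012) and Cry1 by -0.63 ± 0.08 (7.1e-06), each in 5 of 5 triadimefon rats. The circadian list had 2 of 22 higher and 1 lower, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.45). Fatty acid synthesis had 0 of 25 higher and 1 lower, or 1 and 10 adjusted over the list alone, with a mean of -0.264 (camera adjusted p = 9.6e-05, adjusted p = 0.92 with an estimated correlation). Heat shock genes had 0 of 17 changed by limma, with 3849 probe sets at an unadjusted p under 0.05, or 0 higher and 8 lower adjusted over the list alone, with a mean of -0.155 (9.6e-05, and 0.92 with an estimated correlation). Pericentral hepatocyte genes had 0 of 15 changed, or 2 higher and 0 lower adjusted over the list alone, with a mean of 0.041 (0.029, and 0.92 with an estimated correlation), lost without myclobutanil 1 or triadimefon 2 or 3, with means from 0.022 to 0.025 and adjusted p up to 0.097. Cyp2b1 or Cyp2b2 differed by -0.12 with a 95% interval of -0.54 to 0.31 (adjusted p = 0.86) and Ugt2b1 by -0.16 with an interval of -0.53 to 0.22.

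**Figure D3:**
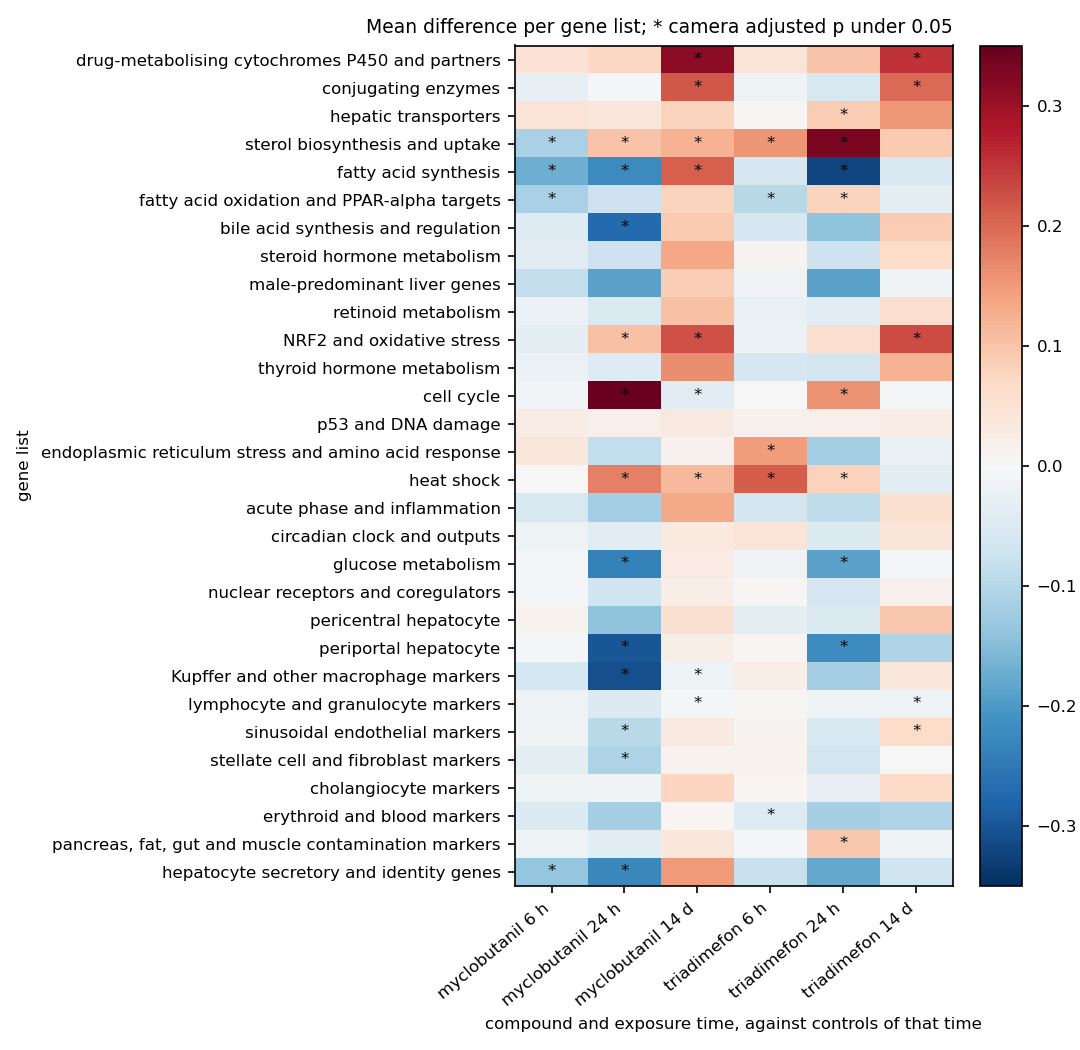
Mean difference from control, in score units, of the 30 gene lists (vertical) in the treatment comparisons (horizontal), with a star where the camera adjusted p is under 0.05. Cell cycle genes at 24 h have a mean of 0.346 with myclobutanil and 0.158 with triadimefon, and the P450 list at 14 days has 0.312 and 0.254.

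Changed in the same direction with both compounds were 61 probe sets at 6 h (49 higher, 12 lower), 1135 at 24 h (347 higher, 788 lower) and 162 at 14 days (152 higher, 10 lower), and 0, 1 and 0 were changed in opposite directions. Independent lists of those sizes would share 0.62 higher and 0.0602 lower at 6 h, 21.1 and 96.7 at 24 h, and 8.87 and 0.504 at 14 days. Both comparisons share controls. What that adds is not shown by 100 simulations without treatment effects (up to 3 shared at 6 h, 0 later). The compounds' differences correlated there (r = 0.53, 0.47 and 0.47), against 0.63, 0.77 and 0.64 as measured. With the controls divided between the compounds, 2 and 3, the median over 20 divisions was 12.5, 229.5 and 39 shared. After quantile normalization 200, 1367 and 227 were shared.

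Whether an effect differed between times was tested directly. The myclobutanil effect on cell division genes was higher at 24 h than at 6 h or 14 days. The effects on Cyp7a1 and Cyp8b1 moved up from 24 h to 14 days. For Cyp7a1 part was lower controls (1.80 to 2.69, then 0.56 to 1.87). With triadimefon, the folding genes Creld2 and Hyou1 were affected more at 6 h than at 14 days, and the effect on Sqle dropped between 24 h and 14 days. Gsta3 and Abcc3, which conjugate and export foreign compounds, gained from 6 h to 14 days with both compounds.

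The myclobutanil effect at 24 h against that at 6 h differed in 306 probe sets upward and 236 downward, 783 and 468 after quantile normalization. Of the cell cycle list 29 of 43 gained and 0 dropped, or 36 and 1 adjusted over the list alone, with a mean of 0.355 (camera adjusted p = 2.8e-45, adjusted p = 0.02 with an estimated correlation). Against 24 h, the effect at 14 days differed in 1073 upward and 344 downward, 496 and 713 after quantile normalization, so the majority turned. There 0 of 43 cell cycle genes gained and 36 dropped, or 0 and 38 adjusted over the list alone, with a mean of -0.382 (1.6e-47, and 0.016 with an estimated correlation). Cyp7a1 differed by 1.95 ± 0.38 (adjusted p = 0.0023), Cyp8b1 by 1.53 ± 0.21 (0.00011) and Cdk1 by -0.83 ± 0.16 (0.0019). The count of 1417 changed without control 2 (677) or 4 (2426) or myclobutanil 1 (921) at 24 h, and without control 4 (797) or myclobutanil 4 (715) at 14 days. Between 14 days and 6 h, 87 differed upward and 17 downward, 108 and 125 after quantile normalization, so the majority turned there too. Gsta3 differed by 1.36 ± 0.22 (adjusted p = 0.00088) and Abcc3 by 0.68 (adjusted p = 0.012). With the ending as a covariate 52 probe sets differed in place of 104, and among arrays of ending 11 it was 9. The count changed without control 2 (43) or 5 (67) or myclobutanil 3 (56) at 6 h, and without control 4 (60) or myclobutanil 2 (63) or 4 (52) at 14 days.

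The triadimefon effect at 24 h against 6 h differed in 171 probe sets upward and 801 downward, 447 and 640 after quantile normalization, and in 22 among arrays of ending 11. Endoplasmic reticulum stress genes had 0 of 34 gaining and 9 dropping, or 0 and 15 adjusted over the list alone, with a mean of -0.265 (camera adjusted p = 0.00027, adjusted p = 0.94 with an estimated correlation), and Creld2 differed by -1.0 ± 0.14 (adjusted p = 5e-05). The count of 972 changed without control 3 (529) or triadimefon 1 (502) or 2 (593) at 6 h, and without control 2 (463) or 4 (1486) or triadimefon 1 (539) at 24 h. Between 14 days and 24 h, 2456 differed upward and 1475 downward, 1790 and 1759 after quantile normalization, and 2253 in all without control 2 at 24 h. Sterol genes had 0 of 22 gaining and 5 dropping, or 0 and 7 adjusted over the list alone, with a mean of -0.239 (0.0003, and 0.92 with an estimated correlation), and Sqle differed by -0.58 (adjusted p = 0.0097) and Cyp7a1 by 1.93 ± 0.38 (adjusted p = 0.0013). Between 14 days and 6 h, 400 differed upward and 207 downward, 791 and 691 after quantile normalization. The count was 325 with the ending as a covariate and 281 among arrays of ending 11. Creld2 differed by -0.99 ± 0.14 (adjusted p = 1.5e-05), Hyou1 by -0.83, Gsta3 by 1.62 and Aldh1a1 by 1.89 ± 0.29 (7.4e-05). Cyp2b1 or Cyp2b2 passed in none of these comparisons of times, with either compound.

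The controls were compared between times to show what changed without treatment, age and time of day included. Some clock genes stood at other levels at 24 h than at 6 h: Nr1d2 (-1.27), Nr1d1 (-1.06) and Dbp (-1.32), which the clock drives, were lower, and Cry1 (0.83) and Npas2 (0.61) were higher. From 6 h to 24 h, 633 probe sets were higher and 230 lower, 751 and 644 after quantile normalization, and 405 in all among arrays of ending 11. Of the circadian list 6 of 22 were higher and 5 lower, or 7 and 5 adjusted over the list alone, with a mean of -0.065, a median of 0.023 and a camera adjusted p of 0.53. The count of 863 was 446 without control 3 at 6 h. From 24 h to 14 days, 16 were higher and 58 lower, 56 and 58 after quantile normalization, with 6105 at an unadjusted p under 0.05. That count of 74 moved with every array left out: 769, 0, 6, 1170 and 1 without controls 1 to 5 at 24 h, and 17, 11, 40, 0 and 0 without controls 1 to 5 at 14 days. From 6 h to 14 days, 368 were higher and 667 lower, 784 and 850 after quantile normalization, and the count of 1035 was 666, 601 and 645 without controls 2, 4 and 5 at 6 h and 596 and 689 without controls 2 and 4 at 14 days. Within ending 11 it was 963, with 533 higher and 430 lower, so the majority turned. The Kupffer list passed upward from 6 h to 24 h, with 1 of 18 higher and 0 lower, also adjusted over the list alone, and a mean of 0.129 (0.021, and 0.99 with an estimated correlation). It passed downward from 24 h to 14 days, with 0 of 18 changed, or 0 and 12 adjusted over the list alone, and a mean of -0.19 (0.00013, and 0.99 with an estimated correlation).

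The p53 and DNA damage list did not pass in any treatment comparison. With myclobutanil at 24 h it had 1 of 18 higher and 3 lower, or 5 and 3 adjusted over the list alone, with a mean of 0.018 (camera adjusted p = 0.14). With triadimefon at 24 h it had 3 of 18 higher and 3 lower, or 4 and 4 adjusted over the list alone, with a mean of 0.019 (0.24).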

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

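The tests of array brightness, of a lower share of all non-hepatocyte cells and of added leukocytes were chosen only after the results they bear on were seen.

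In each group of 5, the highest or lowest rat was set apart where its gap to the nearest rat exceeded 0.71 of the group's range. Of 270 groups tested 18 were set apart, and chance gives about 1 in 20, or 13.5. The correlation with the rest of the group was 0.9895 for control 3 at 6 h (0.9938 to 0.9952 in the others) and 0.9927 for control 2 at 24 h (0.9948 to 0.9955). Control 2 at 24 h was also high in Cyp3a23-3a1 (3.93, others 3.32 to 3.47), Ephx1 (3.83, others 3.11 to 3.24) and Abcc2 (2.66, others 2.02 to 2.11). Triadimefon 5 at 24 h was high in Por (3.06, others 1.79 to 2.15), Cyp4a1 (3.23, others 2.14 to 2.44) and Nr1i2 (1.70, others 1.07 to 1.20) and low in Sqle (1.14, others 1.59 to 1.70) and Fasn (1.21, others 2.20 to 2.35). At 6 h, control 2 was low in Nr1i3 (0.36, others 0.59 to 0.68) and triadimefon 2 in Cyp1a2 (2.89, others 3.12 to 3.19). At 14 days, control 2 was high in Por (1.43, others 0.98 to 1.05), myclobutanil 4 in Cyp1a1 (0.44, others -0.11 to 0.01), myclobutanil 2 in Aldh1a1 (3.43, others 2.51 to 2.75) and triadimefon 4 in Abcb1a (0.78, others 0.27 to 0.41). Triadimefon 1 at 14 days was low in Cyp2b1 or Cyp2b2 (3.05, others 3.77 to 4.03) and Slco1a4 (2.85, others 3.19 to 3.32).

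The effect of a compound differed between times by limma's test of the difference itself. For myclobutanil, 542 probe sets differed between 24 h and 6 h, among them Aldh1a1 (1.05), Sqle (0.70), Mki67 (0.53) and Cyp26a1 (-0.40). Between 14 days and 24 h 1417 differed, among them Cyp7a1 (1.95), Abcb1a (-0.47) and Mki67 (-0.53), and between 14 days and 6 h 104 differed, among them Ugt2b1 (1.23), Ephx1 (0.90), Abcc3 (0.68) and Abcb1a (-0.54). For triadimefon, 972 differed between 24 h and 6 h, among them Aldh1a1 (1.31), Sqle (0.57) and Slco1a4 (0.56). Between 14 days and 24 h 3931 differed, among them Cyp7a1 (1.93), Abcc3 (0.82), Sqle (-0.58) and Alas1 (-0.84), and between 14 days and 6 h 607 differed, among them Aldh1a1 (1.89), Ugt2b1 (1.09), Abcc3 (1.06), Ephx1 (0.80) and Slco1a4 (0.48). With some array left out a call was lost for myclobutanil in Aldh1a1 (15 of the 20 arrays, adjusted p up to 0.094), Mki67 (11 of 20, up to 0.096) and Cyp26a1 (control 5 and myclobutanil 3 and 4 at 6 h and myclobutanil 2 at 24 h, up to 0.064) at 24 h against 6 h. The same held for Abcb1a (myclobutanil 2 and 3 at 24 h and controls 2 and 4 and myclobutanil 2 and 4 at 14 days, up to 0.057) and Mki67 (-0.46, 0.056 without myclobutanil 1 at 24 h) at 14 days against 24 h. At 14 days against 6 h it held for Abcb1a (17 of 20 arrays, up to 0.11), Ephx1 (controls 2 and 5 and myclobutanil 3 at 6 h and controls 3 and 4 and myclobutanil 2 and 4 at 14 days, up to 0.085) and Ugt2b1 (control 2 at 6 h and myclobutanil 2 and 4 at 14 days, up to 0.069). For triadimefon it held for Sqle at 24 h against 6 h (control 3 and triadimefon 3 at 6 h and triadimefon 1 and 3 at 24 h, up to 0.065), and at 14 days against 6 h for Slco1a4 (15 of 20 arrays, up to 0.098) and Ephx1 (0.71, 0.051 without control 2 at 6 h). With the file-name ending as a covariate the calls ended for myclobutanil in Aldh1a1 (1.02, adjusted p = 0.085), Mki67 (0.52, 0.07) and Cyp26a1 (-0.35, 0.089) at 24 h against 6 h and in Abcb1a (-0.50, 0.11) at 14 days against 6 h, and for triadimefon in Slco1a4 (0.47, 0.12) at 14 days against 6 h. The median shift also ended that of Abcb1a (-0.55, 0.051), and replicate numbers as a block that of Slco1a4 (0.48, 0.075).

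Of 100 array splits per comparison, real split included, only the real 1 gave as many calls in 15 of 18 comparisons. For effects between times, such splits do not test equal effects. For each compound against control, the real and highest other counts were 118 and 22, 2628 and 729, and 246 and 13 for myclobutanil, and 284 and 18, 2478 and 1216, and 2076 and 35 for triadimefon. Between the compounds they were 78 and 28, 328 and 188, and 103 and 26. For the myclobutanil effect they were 542 and 205 at 24 h against 6 h, and 1417 and 642 at 14 days against 24 h. For the triadimefon effect they were 972 and 158, 3931 and 1202, and 607 and 177. For the controls at 14 days against 24 h they were 74, or 0 without control 2 at 24 h, and 21. At 14 days against 6 h for myclobutanil, 2 of 100 splits gave as many, and another split gave 891 against the real 104. At 6 h that split parts the arrays by brightness, with 99th percentiles of 2.96 or more against 2.92 or less. At 14 days it puts bright myclobutanil 2 and 4 with controls 1, 2 and 4. In the controls, 4 of 100 splits gave as many at 24 h against 6 h (863 real, 1140 highest) and 2 of 100 at 14 days against 6 h (1035 and 1161). The latter split parts the arrays by brightness, with 99th percentiles of 3.07 or more against 2.92 or less. In these 3 comparisons other splits gave more, so the counts are not put down to treatment or time alone.

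Of 18 Kupffer markers 13 fell with myclobutanil at 24 h. Unequal brightness of the arrays is excluded as the whole cause, since the list mean after quantile normalization was -0.244 (SE 0.048 over arrays), against -0.307 (SE 0.079) as deposited. A lower share of RNA from all non-hepatocyte cells stays open. Markers of mean score over 0.5 had means of -0.351 (14 Kupffer) and -0.124 (17 endothelial and stellate). The permutation of their difference (-0.226, 1-sided p = 6e-05, 100000 resamples) took genes as independent. Fewer Kupffer cells or lower expression in each may lie behind the fall, and neither was tested. The part of the controls at 24 h stays open. Their list mean moved by 0.129 from 6 h and by -0.19 to 14 days, neither passing with an estimated correlation (adjusted p = 0.99).

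Cell cycle genes rose with myclobutanil at 24 h. Unequal brightness is excluded as the whole cause, since the list mean was 0.366 (SE 0.071) after quantile normalization and 0.346 (SE 0.07) as deposited. Dividing leukocytes added to the tissue stay open: the leukocyte marker list had a mean of -0.049 (SE 0.012), but only 1 of its 19 genes has a mean score over 0.5, so the list sits near the background. Division of liver cells may be the source, as a hypothesis from the same data, and the arrays do not tell which cell type expressed these genes.

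Clock genes changed with triadimefon at 14 days. A different clock time at tissue collection may account for it: across 22 clock genes, the treatment difference ran against the difference of controls between 24 h and 6 h, with Pearson r = -0.84 (95% interval -0.96 to -0.53, permutation p = 2e-05) and Spearman rho = -0.67 (permutation p = 0.00094). The correlation is across genes, which are not independent replicates. An effect of the compound on the clock would give the same values, and the labels give no hour of collection, so the explanations stay open.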

How the results depend on the processing

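The fit without the 4 brightest arrays, quantile normalization together with an estimated correlation, and the file-name ending applied to lists and named genes at 6 h were chosen only after the results were seen. Counts below are probe sets changed, compared with the count as reported, and a count within 1.5 times of it is passed over unless stated. A difference that passed in neither setting was counted as unchanged whatever its sign. For a moved count the cause was not tested, except where fewer arrays, fewer probe sets or a stricter limit lower it by construction. Pseudocounts were not run, since the values are not linear. Leaving arrays out was run for lists in the treatment and compound comparisons only, and was not run for lists in the comparisons of times and controls. Signal over background limits the rest: 15290 of 31042 probe sets have a mean score under 0, where a lower level can hardly show, and above 3 the spread within groups grows to 0.218.

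Of 418 calls of named genes, 401 were kept after quantile normalization, 414 after the median shift, 390 with replicate numbers as a block, 375 with the file-name ending as a covariate and 258 in every repeat with 1 array left out; none changed sign in these settings. Within ending 11 alone 12 of 57 were kept and within ending 12 alone 1 of 11, with fewer arrays. Of 72 list calls in the treatment and compound comparisons, 59 were kept after quantile normalization, 65 after the median shift, 70 with the mean of all probe sets of a gene, 1 with an estimated correlation and 22 with quantile normalization and an estimated correlation together. Leaving out each array kept 42. Without the 4 brightest arrays 39 of 48 were kept. With the ending as a covariate 17 of 17 were kept, among arrays of ending 11 alone 8 of 17, and of ending 12 alone 3 of 8. The list of hepatocyte secretory genes reversed between the compounds at 14 days: its mean went from -0.218 to -0.001 after quantile normalization, alone and with an estimated correlation, and camera's direction turned from down to up (adjusted p = 0.99 and 0.98). With myclobutanil at 6 h its mean reversed to 0.115 among arrays of ending 11 (adjusted p = 0.56). The cause was not tested.

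After quantile normalization the counts were 441 for myclobutanil and 828 for triadimefon at 6 h, and 234, 1117 and 292 between the compounds at 6 h, 24 h and 14 days. They were 1251 for the myclobutanil effect at 24 h against 6 h, 233 for that at 14 days against 6 h and 1482 for triadimefon at 14 days against 6 h. For the controls they were 1395 (24 h against 6 h), 114 (14 days against 24 h) and 1634 (14 days against 6 h), and the shared calls at 6 h became 200. Of the reported calls with myclobutanil at 24 h 2285 of 2628 were among the calls after quantile normalization with the same sign, with triadimefon 1915 of 2478 at 24 h and 1721 of 2076 at 14 days. The median shift moved the controls at 14 days against 24 h to 360. Keeping only probe sets above the median level moved the myclobutanil effect at 14 days against 6 h to 177.

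With only the compared groups in the fit, which leaves fewer arrays to estimate the spread, the counts were 1250 for myclobutanil at 24 h, 110 for myclobutanil at 14 days, 491 for triadimefon at 24 h, and 190 and 11 between the compounds at 24 h and 14 days. They were 340 and 843 for the myclobutanil effect at 24 h against 6 h and at 14 days against 24 h, 321 for the triadimefon effect at 24 h against 6 h, and 164, 0 and 596 for the controls at 24 h against 6 h, 14 days against 24 h and 14 days against 6 h; the 0 comes from limma, where the reported fit gives 6105 at an unadjusted p under 0.05. A variance trend with robust moderation gave 46 for the controls at 14 days against 24 h. Array weights gave 204 and 502 for myclobutanil and triadimefon at 6 h, 184 and 757 between the compounds at 6 h and 24 h, 188 and 1132 for the myclobutanil and triadimefon effects at 14 days against 6 h, and 25 and 2144 for the controls at 14 days against 24 h and against 6 h.

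With the file-name ending as a covariate, 12 against all others, the counts were 50 and 110 for myclobutanil and triadimefon at 6 h. They were 52 and 325 for the effects of myclobutanil and triadimefon at 14 days against 6 h. Among arrays of ending 11 alone, which are fewer, they were 20 and 9 for the compounds at 6 h, 8 and 35 between the compounds at 6 h and 14 days, 9 for the myclobutanil effect at 14 days against 6 h, 22 and 281 for the triadimefon effect at 24 h and 14 days against 6 h, and 405 for the controls at 24 h against 6 h. The compounds differed at 6 h in 26 among arrays of ending 12.

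A difference of at least 1.5-fold, if the scale is log2, left 14, 59 and 20 for myclobutanil at 6 h, 24 h and 14 days, 17, 70 and 44 for triadimefon, and 6, 4 and 10 between the compounds. It left 43, 48 and 22 for the myclobutanil effect at 24 h against 6 h, 14 days against 24 h and 14 days against 6 h, 46, 68 and 61 for triadimefon in that order, and 31, 1 and 31 for the controls. An adjusted p under 0.01 left 54, 1130 and 76 for myclobutanil, 113, 944 and 600 for triadimefon, 22, 102 and 27 between the compounds, 207, 396 and 28 for the myclobutanil effect between times, 253, 1249 and 233 for triadimefon, and 318, 0 and 317 for the controls, in the same orders.

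Without the 4 brightest arrays the counts were 52 for myclobutanil at 14 days, 583 and 1360 for triadimefon at 6 h and 24 h, 35 between the compounds at 14 days, 362 and 24 for the myclobutanil effect at 14 days against 24 h and against 6 h, 2522 for the triadimefon effect at 14 days against 24 h, and 0 for the controls at 14 days against 24 h. With controls divided, median shared calls over 20 divisions were 12.5, 229.5 and 39 at 6 h, 24 h and 14 days. Each comparison had fewer controls.

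Leaving out each array in turn gave, from lowest to highest, 79 to 138 for myclobutanil at 6 h, 1717 to 3154 at 24 h and 73 to 408 at 14 days, and 130 to 391, 1159 to 3233 and 1014 to 2185 for triadimefon. Between the compounds it gave 24 to 85, 159 to 457 and 23 to 118. For the myclobutanil effect it gave 369 to 637 at 24 h against 6 h, 677 to 2426 at 14 days against 24 h and 43 to 151 at 14 days against 6 h, and 463 to 1486, 2253 to 5079 and 422 to 825 for triadimefon in that order. For the controls it gave 446 to 1000 at 24 h against 6 h, 0 to 1170 at 14 days against 24 h and 596 to 1416 at 14 days against 6 h.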

Other observations

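The test of body temperature was written down before its result was seen, and the bound that leaves it open was chosen only after.

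Cirbp and Rbm3, whose transcripts increase when cells cool, moved in opposite directions at different times of triadimefon. Against control, Cirbp changed by -0.19 (adjusted p = 0.00037) and Rbm3 by -0.34 (adjusted p = 0.00036) at 6 h, and by 0.14 (adjusted p = 0.0051) and 0.31 (adjusted p = 0.00031) at 14 days. At 24 h they changed by -0.07 (adjusted p = 0.15) and -0.17 (adjusted p = 0.047). With myclobutanil they differed by 0.03 (adjusted p = 0.89) and 0.04 (adjusted p = 0.94) at 6 h, by -0.10 (adjusted p = 0.033) and -0.07 (adjusted p = 0.45) at 24 h, and by 0.04 (adjusted p = 0.57) and 0.16 (adjusted p = 0.17) at 14 days. These genes were first seen among the largest differences between the compounds at 6 h.

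A warmer body in the triadimefon rats at 6 h may explain lower Cirbp and Rbm3 beside higher heat shock genes. If so, rats with more of the heat shock genes would have less of the cold genes within groups, a negative correlation. Over the 15 arrays at 6 h, after group means were taken off, Pearson r was 0.08 (permutation p = 0.78, 95% interval -0.45 to 0.52) and Spearman rho 0.14 (permutation p = 0.62). Without the 2 arrays farthest from the median r was -0.20, and it was 0.49 over the 7 arrays of file-name ending 11 and -0.07 over the 6 of ending 12. The bound set beforehand against this explanation was met, since the interval excluded a strong negative correlation, yet that bound was wrong for this design. The heat shock list varied within groups with an SD of 0.065, against a difference of 0.212 between the compounds, so a shift shared by a whole group would leave no trace within groups.

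Some list means rested on a single rat. In the triadimefon rats at 24 h, the mean of fatty acid oxidation genes was 0.078 with rat 5 and -0.011 without it. The mean of pancreas, fat, gut and muscle markers, of which 0 of 24 rose and 1 fell, was 0.094 with rat 2 and -0.02 without it. Neither call passed with an estimated correlation (adjusted p = 0.92 for both), and the latter did not pass after quantile normalization (0.11). Rat 5 was also set apart by high Cyp4a1 and low Fasn.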
